A study of Mus musculus with 46 samples.

How the data were processed

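Reduced representation bisulfite sequencing (RRBS) reads cytosine methylation in fragments cut by the enzyme MspI. It was applied to satellite cells, the stem cells of skeletal muscle, from C57BL/6 mice of 8.5 to 9 months, and to muscle tissue. The hind-limb muscles had been injured by piercing with a 23-gauge needle, and the cells were sorted as VCAM1 positive and negative for CD31, CD45 and Sca1. A further 5 libraries came from heart, liver, spleen and cerebellum, which makes 46 libraries in all. The labels put 41 libraries into 10 groups of satellite cells or muscle.

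The deposited tables give percent methylation, from 0 to 100 with 1 decimal, of regions 100 bp wide in each library. Per the submitters' processing notes, the tools were Trim Galore 0.6.0, cutadapt 1.18, FastQC 0.11.7, Bismark 0.13.1, Bowtie2 and methylKit 1.10.0, on the mouse genome build mm10. The settings of these tools and the rule by which the authors chose the regions are not stated. A pair of tables holds the de novo set, another pair the demethylation set, and the fifth the pregnancy set. Within each pair, 1 table carries MuSC, ACT, muscle, MuSC_2mo and the 5 tissue libraries, and the other carries CSC, CSC_2mo, Ser_inj, MuSCP and MuSCP_2mo. The tables were joined by position. Comparisons that cross from one table to the other therefore set values from separate deposited tables side by side. The authors' tables hold no read counts, so the depth behind each value is unknown and no interval for it could be given.

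In most libraries a single value close to the library's mean over the table repeats many times. Such a value was taken as a filled empty cell and treated as missing when it repeated at least 10 times and lay within 0.1 points of the mean of the other values, or, where no value did, when it was at least 3 times as frequent as the next most frequent value. This rule was inferred from the values and is stated nowhere in the labels. Filled cells made up at most 35.2% of a MuSC library, 16.9% of an ACT library and 46.2% of a MuSCP library.

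Each region was compared between groups with limma 3.58.1 in R 4.3.3, by linear models on the percent scale. At least 2 values in each group and a Benjamini-Hochberg adjusted p below 0.05 over the regions tested were required. MuSC, ACT, MuSC_2mo and muscle were compared with each other in a shared model. Comparisons of CSC, CSC_2mo, Ser_inj, MuSCP and MuSCP_2mo used a model of these groups with MuSC and ACT. MuSC_2mo and muscle were compared with CSC_2mo in a model without MuSC and ACT, and ACTP with MuSCP in a model of their own. Counts from different models therefore rest on different spreads. Means over regions were compared over the regions with a value in every library of both groups, by a two-sided exact permutation test of the library means. These p-values were adjusted over 35 comparisons. Differences between differences were set against two-sided exact permutation of labels within each contrast and adjusted over 6 tests. This permutation assumes no difference within either contrast, so a small p can come from a single contrast. The share of the ACT shift is 100 times a group's difference from MuSC over that of ACT, with a 95% bootstrap interval over libraries. Counts of gene lists were compared by a two-sided Fisher's exact test over clusters of regions within 1 kb, adjusted over 16 lists. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

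Regions were placed in genes by the annotation table supplied with 21900 protein-coding genes. A region was given to a gene that it overlaps, or else to the nearest gene within 50 kb. Strand was not used, so a distance runs to the nearer end of the gene, which need not be its start. Promoters, exons, introns and CpG islands were not assigned, because neither a genome sequence nor transcript models were used here. The 16 gene lists were written before the data were examined, with 531 symbols, of which 523 were found. They cover myogenic regulators, sarcomere and costamere, excitation and calcium, quiescence, the Notch, Wnt, and TGF beta and BMP pathways, growth factors and mTORC1, cell cycle, DNA methylation machinery, energy metabolism, immune, endothelial and fibro-adipogenic markers, imprinted genes, and developmental transcription factors.

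Genes were named by a rule fixed before the data were examined. In each comparison these were the 10 regions with the largest difference among those called whose groups did not overlap in any library, with 1 region per gene. Up to 4 genes of each list were added, called or not, by the size of their difference. The regions named in ACT against MuSC were followed through the other comparisons. Regions that run against the direction of their set were counted, and the 2 largest named. Some genes that this rule names are not reported here. In ACT against MuSC, the called examples printed are among those whose call did not hang on any 1 library, and calls in the other comparisons were not chosen so.

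The model was tested on simulated data built from the spread between replicates. With 200 changed regions of the de novo set, ACT against MuSC recovered 6.67% of differences of 20 points, 43.2% of those of 40 points and 93.9% of those of 80 points, and 24.6% of calls were false. With 2686 changed regions the shares were 34.7%, 75.5% and 99.3%, and 1.16% of calls were false. CSC_2mo against MuSC with 200 changed regions recovered 3.39%, 12.7% and 76.8%, and with 2686 changed regions 8.15%, 46.4% and 93.3%.

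Alternatives tried were a model with only the 2 groups compared, leaving out each library, libraries centred by their median, averaging within 1 kb, an exact permutation test per region, medians over regions, a logit scale with an offset of 0.01, genes within 10 kb only, replicate numbers as a block, a difference of 10 points or more, only regions with every value, every region with a value, no X and Y, and MuSC libraries split in 2 parts. After the data were examined, filled cells kept as deposited, the omission of MuSCP libraries 1 and 2, the comparisons of MuSC_2mo and muscle with CSC_2mo, and the sums of neighbouring regions were added. In 2 tables, 4 columns each match no sample and were left out, 8 in all. Libraries were checked for duplicates, and none was found. The sequencing reads were not used here. The condition for arguing against DNA of muscle fibres in the ACT libraries was made stricter after the value was known, and a partial share of such DNA then stayed open. For spleen a stricter condition on the sums of neighbouring regions was also set after its value was known, and was withdrawn, since the pairs hold few of the regions and the lower spleen differed from MuSC by −3.52 points outside them too. These sums still limit what the spleen values can show.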

Results

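Methylation was measured by RRBS in satellite cells, the stem cells of skeletal muscle, before and after needle injury of the hind limb, in virgin and pregnant mice. The groups, in the names of the labels, were MuSC (non-activated cells, n = 5), ACT (activated cells, n = 5), MuSC_2mo (cells 2 months after injury, n = 4), muscle (tissue, n = 4), CSC (cells of the contralateral limb, n = 3), CSC_2mo (contralateral, 2 months after injury, n = 3) and Ser_inj (cells after serum injection, n = 4). The pregnancy groups were MuSCP (non-activated, n = 5), MuSCP_2mo (2 months after injury, n = 4) and ACTP (activated, n = 4). The name MuSCP_2mo does not say whether these mice were pregnant at sampling. A comparison of MuSCP_2mo with MuSCP may therefore mix time after injury with the state of pregnancy. Heart, liver and a spleen at 1 week of age, and a spleen and the cerebellum at 20 weeks, gave 1 library each and no replicates. The design text states separate mice with at least 4 in each group, while CSC and CSC_2mo hold 3 libraries here. Values are percent methylation of 100-bp regions, and the depth behind them is unknown.

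The de novo set held 2984 regions, of which 1406 (47.1%) overlapped a gene, 794 lay within 50 kb of a gene and 149 were on the X chromosome. The demethylation set held 2592 regions, 1218 (47.0%) of them in a gene. The pregnancy set held 1143 regions, 565 (49.4%) of them in a gene. No region was in both the de novo and the demethylation set. All 2984 de novo regions had a higher mean in ACT than in MuSC, and 2591 of 2592 demethylation regions had a lower one, so both sets were chosen on the libraries that this comparison uses. Differences between ACT and MuSC in these sets are therefore not independent evidence that the cells differ.

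The first comparison, ACT against MuSC, asks which regions differ between activated and resting satellite cells. Etv6, which encodes an ETS-family repressor of blood-forming cells, held a de novo region on chromosome 6 (134128701 to 134128800, within the gene) at 70.3% ± 17.03 (SD, n = 5) in ACT and 0% ± 0 (n = 5) in MuSC. At Tbx1, a T-box factor of head muscle and heart development, the level was 58.5% ± 3.41 (n = 5) in ACT and 8.38% ± 10.8 (n = 4) in MuSC. Lgr6, a receptor for R-spondins, stood at 78.1% ± 15.1 (n = 5) against 9.03% ± 18.1 (n = 4), and Svil, an actin-binding protein of the costamere, at 77.0% ± 21.4 (n = 5) against 9.72% ± 8.02 (n = 4). Nphp4, a protein of the primary cilium, stood at 68.8% ± 9.41 (n = 4) against 1.30% ± 1.56 (n = 4). The limma adjusted p was 0.000789 for Etv6 and Nphp4, 0.00186 for Tbx1 and Lgr6, and 0.00226 for Svil. Further regions of large difference lay at Lipc, Clcn4, Agbl2, Ppm1k and, 8139 bp from the gene, Cd6. Among factors of muscle cells, Pax3, which marks embryonic muscle progenitors, held 64.6% ± 13.6 (n = 5) in ACT and 27.3% ± 27.1 (n = 5) in MuSC (adjusted p 0.0101). Atp2a1, the calcium pump of fast fibres, held 91.3% ± 7.26 (n = 5) against 45.1% ± 22.1 (n = 4, adjusted p 0.00462). Jag2, a ligand of Notch, and Fgf6, a growth factor of muscle, held 38.6% ± 10.5 and 51.0% ± 10.4 in ACT (adjusted p 0.00953 and 0.00857).

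In the demethylation set, a region on chromosome 15 (75736101) lay 9301 bp from Mafa, the gene of an insulin-gene activator. It held 22.1% ± 14.3 (n = 5) in ACT and 88.4% ± 18.1 (n = 5) in MuSC. Emcn, a surface glycoprotein of endothelial cells, held 31.7% ± 6.03 (n = 5) against 88.4% ± 19.2 (n = 5). Dtx1, an E3 ligase of the Notch pathway, held 17.7% ± 18.4 (n = 5) against 77.5% ± 19.3 (n = 4), and the adjusted p was 0.00326 for each of Mafa, Emcn and Dtx1. Taf5l, a subunit of a histone acetyltransferase complex, held 17.3% ± 8.93 (n = 5) against 86.8% ± 19.3 (n = 5, adjusted p 0.00145). Ryr1, the calcium release channel of muscle, held 32.2% ± 19.2 (n = 5) against 76.6% ± 28.9 (n = 4, adjusted p 0.0123). Ppargc1a, a regulator of mitochondria, held 23.4% ± 17.1 (n = 4) against 68.2% ± 24.7 (n = 4, adjusted p 0.0126). Ccnb2, a mitotic cyclin, held 50.1% ± 22.7 (n = 5) against 58.5% ± 42.02 (n = 4) and did not pass (adjusted p 0.603), and without MuSC library 3 its difference had the other sign. The other regions of largest difference lay at Plcd3, Recql, Hgd, Olfr943, Ldc1, Lrrc75a, Dnajc6 and Ddx1.

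By limma, 2088 of 2984 de novo regions were higher in ACT and none lower (2263 at an unadjusted p under 0.05), and 1659 of 2592 demethylation regions were lower (1875 unadjusted). With only these groups in the model the counts were 1575 and 718, and with replicate numbers as a block, which do not pair the libraries, 0 and 0. The exact permutation test per region also called 0 and 0, and the logit scale lowered the demethylation count. The libraries of both groups did not overlap in 866 de novo regions (29.0%) and in 557 demethylation regions (21.5%). Over the 801 de novo regions with every value the mean was 57.4% ± 0.746 in ACT and 22.7% ± 1.64 in MuSC, a difference of 34.7 points (two-sided exact permutation p 0.00794, adjusted 0.0278 over 35 comparisons). Over 694 demethylation regions the means were 32.4% ± 1.35 and 67.0% ± 2.78, a difference of −34.5 points (exact permutation p 0.00794, adjusted 0.0278). A share of 46.4% of MuSC values in the de novo set stood at exactly 0 or 100, against 4.75% in ACT and 1.25% in muscle. This share was 46.8% in CSC, 45.7% in MuSCP and 60.1% in MuSCP_2mo, and 23.5% in Ser_inj, 16.2% in CSC_2mo and 11.1% in MuSC_2mo.

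**Figure D1:**
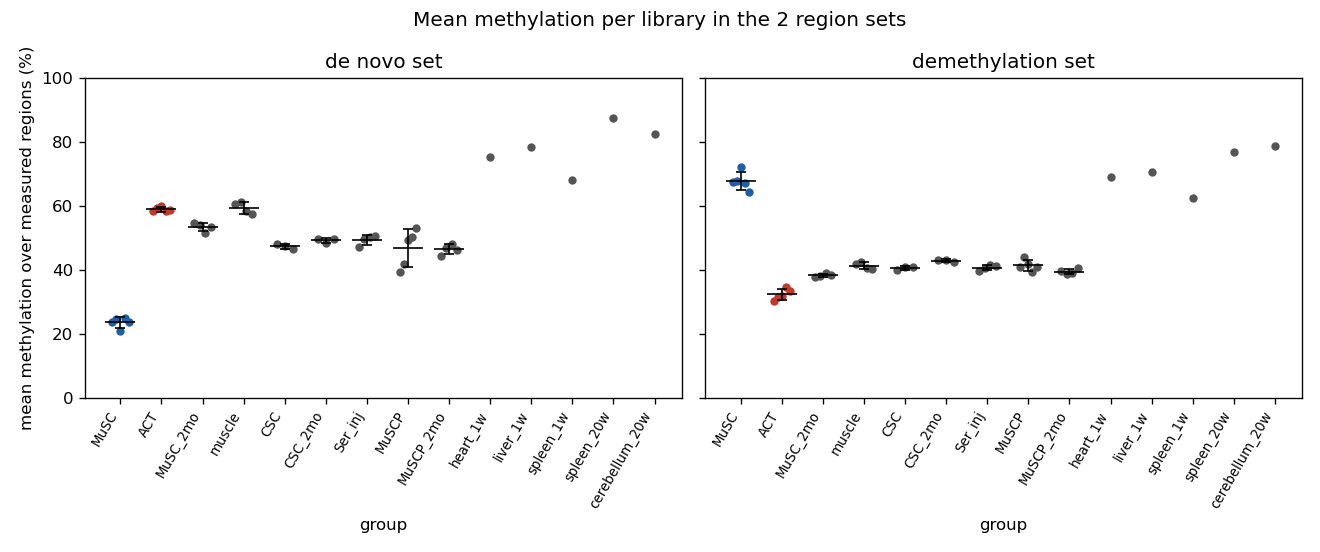
Mean methylation (percent, vertical axis) over the measured regions of each set by group (horizontal axis), with 1 point per library and bars for the group mean ± SD. In the de novo set the MuSC libraries averaged 23.6% and every other group of satellite cells or muscle averaged 46.5% or more.

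**Figure D2:**
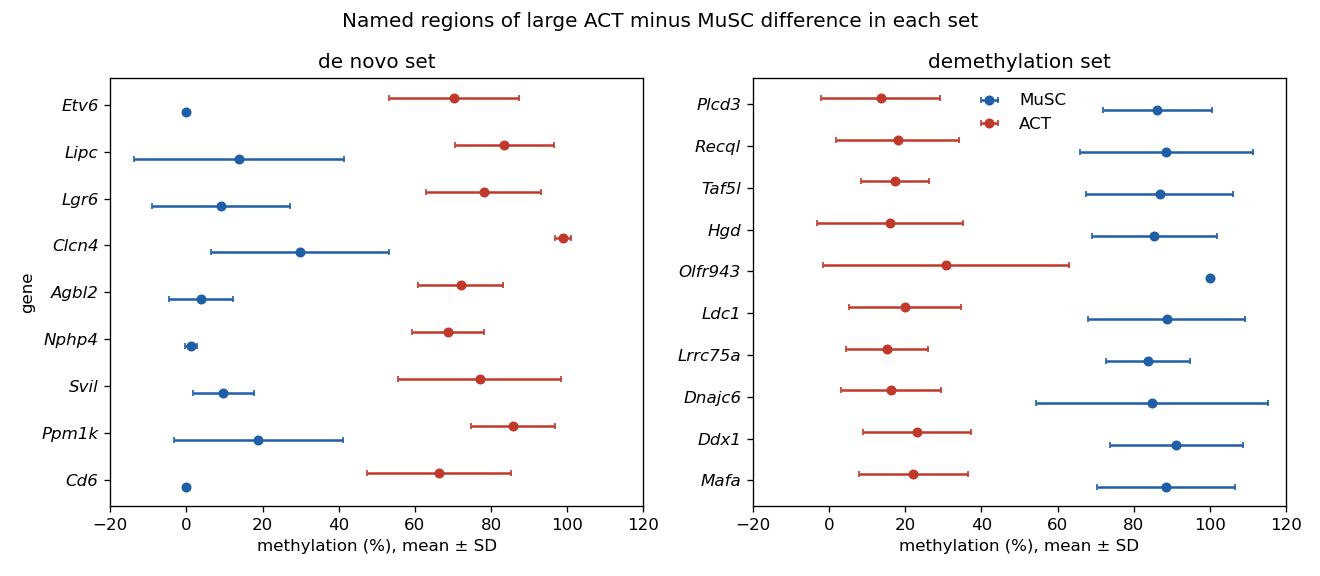
Methylation (percent) in ACT and MuSC of regions of large difference at named genes, with points for the group mean and bars for ± SD over the libraries. Etv6 stood at 70.3% in ACT and 0% in MuSC, and Taf5l at 17.3% and 86.8%.

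Regions of the opposite sets lay side by side. Taf5l held a de novo region on chromosome 8 at 123994001 and a demethylation region at 123993801, with MuSC at 10.2% ± 18.5 (n = 5) in the first and 86.8% ± 19.3 (n = 5) in the other. Notch3, a receptor of satellite cells and mural cells, held such a pair at 19.9% ± 24.4 and 61.3% ± 22.6 (n = 4) in MuSC. At Nphp4 the pair stood at 1.30% ± 1.56 (n = 4) and 86.0% ± 18.99 (n = 5). Of 470 neighbouring regions with starts at most 300 bp apart, 380 belonged to opposite sets (80.9%), against 49.5% of neighbours more than 1000 bp apart. Shuffling the set labels gave 234 such pairs on average and 273 at most in 10000 shuffles (one-sided permutation p 1e-04, the smallest they can give). Pairs with starts 200 bp apart were of opposite sets in 204 of 214 cases.

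In these 380 pairs the percentages of both regions in a library mostly added up to about 100 or less. The median sum was 100 points in MuSC, 93.3 in ACT and 93.6 in muscle, which alone does not mark the pairs, since opposite neighbours more than 1000 bp apart had medians of 96.7, 90.4 and 100. The upper quartile of the pairs lay between 97.8 and 100 in all 37 satellite cell and muscle libraries of the 2 sets, and that of the distant neighbours was 117.4. A sum within 1 point of 100 was found for 36.9% of library values, against 6.92% in the distant neighbours. This share ran from 6.25% to 71.3% over the libraries, with 8.68% in muscle, where few values stand at 0 or 100, and 60.7% in MuSCP_2mo, and it was 13.3% in distant neighbours in MuSC. The heart, liver, spleen and cerebellum libraries had median sums of 147.5 to 187 points in the same pairs. Within a library, the values of both regions correlated at −0.629 to −0.378 across pairs in satellite cells and muscle and at 0.210 to 0.645 in the tissues, where pairs are not independent replicates, and by group at −0.0176 to 0.0236 in distant neighbours in satellite cells and muscle. Pairs held 12.7% of the de novo and 14.7% of the demethylation regions, and the regions named at Agbl2, Ddx1, Ldc1, Nphp4, Notch3, Ppm1k and Taf5l were among them. Given the negative correlation within libraries, the de novo and demethylation values of such pairs are not independent of each other.

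**Figure D3:**
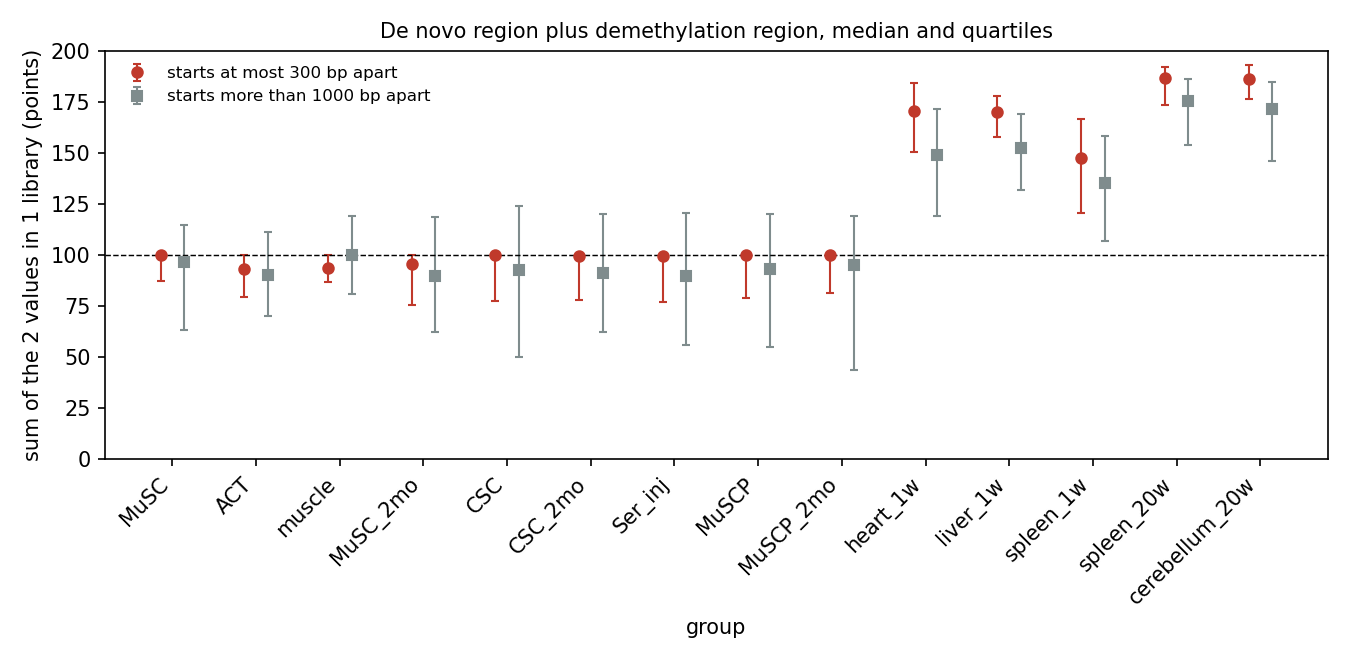
Sum of the percent methylation of a de novo and a neighbouring demethylation region in 1 library (points, vertical axis) by group (horizontal axis), as median with bars for the quartiles, for starts at most 300 bp apart (circles) and more than 1000 bp apart (squares). Nearby pairs had upper quartiles at 100 in every satellite cell and muscle group and median sums of 147.5 or more in the tissue libraries.

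At 2 months after injury, MuSC_2mo against MuSC asks whether a difference lasts. Rftn1, a lipid-raft protein, held a de novo region at 92.8% ± 8.44 (n = 4) in MuSC_2mo and 5.74% ± 10.5 (n = 5) in MuSC, and Nphp4 held 83.9% ± 10.8 (n = 4) against 1.30% ± 1.56 (n = 4), each with an adjusted p of 7.16e-05. Slc25a33, a mitochondrial nucleotide carrier, held 97.8% ± 3.87 (n = 3) against 5.55% ± 11.1 (n = 4, adjusted p 0.000354). Of the demethylation regions, Emcn held 12.6% ± 9.07 (n = 3) against 88.4% ± 19.2 (n = 5, adjusted p 0.000527) and Ddx1, an RNA helicase, 11.4% ± 3.10 (n = 4) against 91.2% ± 17.6 (n = 4, adjusted p 0.000442). Limma called 1024 of 2617 de novo regions higher (1382 unadjusted) and 816 of 2252 demethylation regions lower (1115 unadjusted). These counts were 503 and 121 with only these groups in the model, and 0 and 0 with replicate numbers as a block. The de novo mean was 51.7% ± 1.55 in MuSC_2mo and 22.8% ± 2.31 in MuSC over 674 regions, and the demethylation mean 38.1% ± 0.872 and 67.3% ± 3.27 over 566 (exact permutation p 0.0159 for each, the smallest possible, adjusted 0.0278). Against ACT, limma called 0 regions in either set (277 de novo and 216 demethylation regions unadjusted), and 1 in each in a model of these groups alone. MuSC_2mo lay below ACT by −4.70 points in the de novo set (52.3% ± 1.25 and 57.0% ± 1.15 over 1438 regions) and above it by 6.02 points in the demethylation set (39.5% ± 0.378 and 33.4% ± 1.89 over 1293), each with an exact permutation p of 0.0159, adjusted 0.0278.

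Muscle tissue served as a reference for DNA of other cells. Pcsk6, a proprotein convertase, held 84.2% ± 8.30 (n = 4) in muscle and 0% ± 0 (n = 4) in MuSC, and Col5a1, a fibrillar collagen, 83.0% ± 11.8 (n = 4) against 0% ± 0 (n = 4), each with an adjusted p of 9.37e-05. Tbx15, a T-box factor of muscle and fat, held a demethylation region on chromosome 3 (99257001) at 13.4% ± 6.59 (n = 4) in muscle and 99.9% ± 0.134 (n = 5) in MuSC (adjusted p 0.00198). Limma called 1561 of 2607 de novo regions higher and 547 of 2280 demethylation regions lower than in MuSC (1748 and 966 unadjusted). The 547 fell to 274, 252, 258 and 268 without muscle library 1, 2, 3 and 4, to 305 with only these groups in the model and to 0 with replicate numbers as a block, and were 843 with filled cells kept. With libraries centred the counts were 739 and 1210. Against ACT it called 0 regions in either set (172 and 160 unadjusted), but 9 and 69 with only these groups in the model and 4 de novo regions among those with every value. The de novo mean of muscle was 58.1% ± 1.65 and that of ACT 57.2% ± 0.898 over 1709 regions, a difference of 0.919 points within the spread between libraries (exact permutation p 0.270, adjusted 0.295). Muscle exceeded ACT by 7.90 points in the demethylation set (exact permutation p 0.0159, adjusted 0.0278).

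The contralateral limb asks whether cells away from the wound differ. Wfdc8 and Rpl28, a ribosomal protein, held de novo regions at 100% ± 0 (n = 3) in CSC, and at 7.40% ± 11.2 and 7.70% ± 10.2 (n = 4) in MuSC, each with an adjusted p of 0.0336. Igf2r, an imprinted receptor, held 100% ± 0 (n = 3) against 17.6% ± 17.3 (n = 4, adjusted p 0.0439). Epcam, an epithelial adhesion protein, held a demethylation region at 0.733% ± 1.27 (n = 3) against 89.3% ± 16.7 (n = 4, adjusted p 0.0343). Limma called 26 of 2711 de novo and 39 of 2364 demethylation regions in CSC against MuSC (566 and 593 unadjusted). Simulated de novo data with 200 changed regions gave 36.6% false calls in this comparison, and with 2686 changed regions 0.696%. The de novo count was 0 without MuSC library 1, 2 or 5, and the demethylation count was 0 without MuSC 2, CSC 1 or CSC 3, so the calls at these genes hung on single libraries. These counts were 42 and 0 with only these groups in the model, 7 and 5 over regions with every value, 60 and 111 with filled cells kept, and 0 and 0 with replicate numbers as a block. In CSC_2mo against MuSC it called 0 in either set (537 and 445 unadjusted; 3 de novo regions in a model of these groups alone), and in CSC_2mo against CSC 0 (172 and 145 unadjusted). The de novo mean was 45.7% ± 2.00 in CSC against 22.7% ± 1.36, and 48.1% ± 1.07 in CSC_2mo against 22.9% ± 1.58, with an exact permutation p of 0.0357 for each, adjusted 0.0481. The demethylation means differed from MuSC by −26.1 points in CSC and −25.6 points in CSC_2mo (exact permutation p 0.0357, adjusted 0.0481). CSC_2mo stood at 49.0% ± 1.37 and CSC at 47.3% ± 1.41 in the de novo set (exact permutation p 0.3, where 0.1 is the smallest possible with 3 against 3), and they differed by 2.38 points in the demethylation set (exact permutation p 0.1). Against ACT, CSC differed by −10.5 and 7.68 points in the de novo and demethylation sets (exact permutation p 0.0357), the latter 2.83 points with medians over regions (exact permutation p 0.143). Limma called 0 regions there (253 and 169 unadjusted), and 19 and 3 in a model of these groups alone.

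Serum injection asks whether serum alone shifts the cells. Mafa held 6.55% ± 13.1 (n = 4) in Ser_inj and 88.4% ± 18.1 (n = 5) in MuSC, and Actn4, an actin crosslinker, 5.78% ± 8.92 (n = 4) against 81.9% ± 17.5 (n = 4), each with an adjusted p of 0.03. Gdf10, a BMP family ligand, held 0% ± 0 (n = 4) against 82.0% ± 24.6 (n = 4, adjusted p 0.0435). Against ACT, 3 demethylation regions were higher, at Txnrd3 (100% ± 0, n = 3, against 9.20% ± 9.42, n = 5, adjusted p 0.0106), Sipa1l2 (adjusted p 0.024) and Zfp120 (adjusted p 0.043). Limma called 26 of 2569 demethylation regions lower than in MuSC (636 unadjusted) and 0 of 2948 de novo regions (656 unadjusted). The 0 became 63 with only these groups in the model and 57 with filled cells kept, where the 26 became 9 and 112. The 26 calls fell to 0 without Ser_inj library 1, 2 or 3, and the 3 calls against ACT to 0 without Ser_inj 2, 3 or 4. The de novo mean was 47.8% ± 1.71 against 22.9% ± 1.61 in MuSC, and the demethylation mean differed by −27.0 points (exact permutation p 0.0159 for each, adjusted 0.0278). Ser_inj differed from ACT by −8.90 and 7.78 points (exact permutation p 0.0159), with 0 de novo regions called (133 unadjusted). A model of these groups alone called 5 de novo and 9 demethylation regions between them.

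Pregnancy was compared in resting cells first. Tbx1 held 81.0% ± 20.4 (n = 5) in MuSCP and 8.38% ± 10.8 (n = 4) in MuSC (limma adjusted p 0.0484). A region 7784 bp from Cep41, the gene of a ciliary protein, held 81.0% ± 24.2 (n = 5) against 6.46% ± 8.23 (n = 5, adjusted p 0.0484). Nid2, a basement-membrane protein, held a demethylation region at 1.23% ± 2.14 (n = 3) against 90.8% ± 18.4 (n = 4), and Emcn 6.62% ± 10.5 (n = 5) against 88.4% ± 19.2 (n = 5), each with an adjusted p of 0.00929. Limma called 6 of 2954 de novo and 83 of 2555 demethylation regions (672 and 690 unadjusted). The 6 calls, those at Tbx1 and Cep41 among them, fell to 0 without any 1 of MuSC 1, 2 or 3 or MuSCP 2, 3 or 4, rose to 62 without MuSCP 5, and were matched by other splits of the libraries (6 of 100). The 83 were 46, 54, 39, 41 and 145 without MuSCP 1 to 5, 4 without MuSCP 1 and 2 together, 7 with only these groups in the model (where the 6 fell to 0) and 0 with replicate numbers as a block or by the exact permutation test per region, against 125 with regions within 1 kb averaged and 202 with filled cells kept. The de novo mean was 46.0% ± 5.04 in MuSCP against 23.1% ± 2.58 in MuSC, and the demethylation mean differed by −25.2 points (exact permutation p 0.00794, adjusted 0.0278). MuSCP differed from ACT by −10.7 and 8.68 points (exact permutation p 0.00794), the latter 4.28 points with medians over regions (exact permutation p 0.198), with 0 regions called by limma in either set (225 and 151 unadjusted).

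The pregnancy group 2 months after injury, MuSCP_2mo, was compared next. Il20rb, a cytokine receptor chain, held 100% ± 0 (n = 4) in MuSCP_2mo and 9.25% ± 16.1 (n = 4) in MuSC (adjusted p 0.0204), and Mafa 0% ± 0 (n = 4) against 88.4% ± 18.1 (n = 5, adjusted p 0.00951). Against MuSCP, the called regions lay at Pappa, a protease that frees insulin-like growth factors (100% ± 0 against 0% ± 0, n = 3 each, adjusted p 0.0441), Hnf4g (0% ± 0, n = 4, against 90.3% ± 12.9, n = 4, adjusted p 0.0172) and Apoa4 (0.475% ± 0.950, n = 4, against 83.0% ± 22.2, n = 4, adjusted p 0.0441). Limma called 80 of 2603 de novo and 173 of 2260 demethylation regions against MuSC (575 and 666 unadjusted). The 80 were 18 without MuSC 3, 50 without MuSC 1 and 53 without MuSC 4, and the 173 were 94 without MuSC 3 and 87 without MuSCP_2mo 3. With only these groups in the model 33 and 30 were called, and 0 with replicate numbers as a block. With libraries centred by their median the de novo count rose and the demethylation count fell, and with filled cells kept the reverse held. Against MuSCP it called 3 of 2585 de novo regions, 1 higher and 2 lower (320 unadjusted), and 0 demethylation regions (254 unadjusted). On the logit scale it called 18 and 28, and in a model of these groups alone 0 and 0. As many as these 3 were called in 40 of 100 splits of the libraries, and 0 without MuSCP 2, MuSCP 4 or MuSCP_2mo 2, so chance was not excluded at Pappa, Hnf4g and Apoa4. Simulated data with 200 changed regions gave 41.4% false calls in this comparison. The de novo mean was 44.2% ± 2.41 against 22.1% ± 2.03 in MuSC (exact permutation p 0.0159, adjusted 0.0278), and the demethylation mean differed by −28.2 points. MuSCP_2mo stood at 44.6% ± 3.77 and MuSCP at 47.3% ± 6.82 in the de novo set (exact permutation p 0.540), and they differed by −1.76 points in the demethylation set (exact permutation p 0.397). The latter was −2.002 points over every region with a value and −2 points with filled cells kept (exact permutation p 0.0476 each).

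The distance of each group from MuSC was set against that of ACT. The de novo share was 99.1% for muscle (bootstrap 95% interval 94.5 to 104), 85.4% for MuSC_2mo (81.3 to 89.1), 72.6% for CSC_2mo, 72.1% for Ser_inj, 67.9% for CSC, 67.4% for MuSCP_2mo and 67.0% for MuSCP (53.6 to 78.1). The demethylation shares were 84.8% for MuSC_2mo (80.9 to 88.1), 81.3% for MuSCP_2mo, 77.5% for muscle, 77.3% for Ser_inj, 75.6% for CSC, 73.6% for MuSCP and 71.9% for CSC_2mo (69.2 to 74.6). Regions chosen on chance values of MuSC and ACT alone would give shares of 71.7% in the de novo and 80.3% in the demethylation set by calculation from the spread, and of 62.4% and 76.1% in simulated data. The shares of CSC, CSC_2mo, Ser_inj, MuSCP and MuSCP_2mo ran from 67.0% to 72.6% and from 71.9% to 81.3%, and the demethylation share of muscle was 77.5%. How much of these shares comes from the choice of the regions is therefore not settled. At Pax3 the level was 65.0% ± 2.23 (n = 4) in MuSC_2mo, 71.1% ± 1.19 (n = 4) in muscle, 52.0% ± 9.05 (n = 3) in CSC_2mo and 39.5% ± 25.7 (n = 4) in Ser_inj. MuSC_2mo exceeded CSC_2mo by 4.31 points in the de novo set and differed by −4.26 points in the demethylation set, and muscle differed from CSC_2mo by 9.85 and −2.05 points (exact permutation p 0.0571 for each, the smallest possible, adjusted 0.0667). These comparisons with CSC_2mo were added after the data were examined. Limma called 0 regions in MuSC_2mo against CSC_2mo (99 and 108 unadjusted). In muscle against CSC_2mo it called 1 de novo region, lost without any 1 muscle library, at Ociad2 (67.5% ± 5.84, n = 4, against 5.83% ± 9.76, n = 3, adjusted p 0.0421), and 0 demethylation regions (89 unadjusted). A model of these groups alone called 112 de novo and 56 demethylation regions, and 4 de novo regions were called among those with every value.

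**Figure D4:**
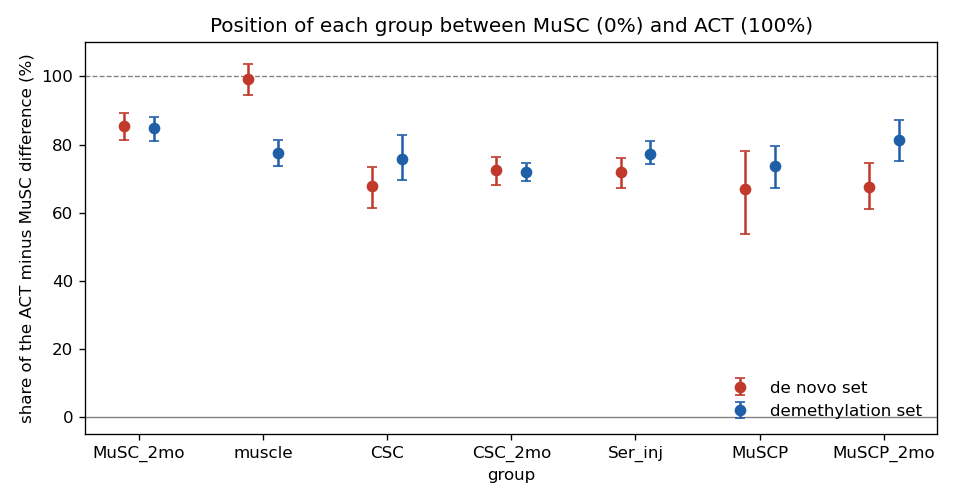
Share of the ACT shift from MuSC (percent, vertical axis) of each group (horizontal axis) in the de novo and demethylation sets, with bars for the bootstrap 95% interval over libraries. All groups lay between 67.0% and 99.1%.

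The differences of the groups at 2 months from MuSC, CSC and MuSCP were set against each other. MuSC and MuSCP are non-activated cells and CSC cells of the contralateral limb, so these contrasts differ in kind. MuSC_2mo minus MuSC was 28.9 points in the de novo set and MuSCP_2mo minus MuSCP −0.965 points over 122 shared regions, a difference of 29.9 points (two-sided exact permutation p 0.00705, adjusted 0.0212 over 6 tests). Against CSC_2mo minus CSC, at 2.12 points, the difference was 26.8 points (exact permutation p 0.0151, adjusted 0.0226). The demethylation differences were −26.0 points (exact permutation p 0.0121, adjusted 0.0226) and −31.7 points (exact permutation p 0.00317, adjusted 0.0190). MuSC, on whose libraries the regions were chosen, enters only the first contrast of these 4 tests and enlarges it, so they are not independent evidence of a difference between animals or limbs. The permutation assumes no difference within either contrast, so MuSC_2mo minus MuSC alone could give these p-values. CSC_2mo minus CSC and MuSCP_2mo minus MuSCP differed by 3.65 points in the de novo set (exact permutation p 0.360) and 3.84 points in the demethylation set (exact permutation p 0.106, adjusted 0.128).

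Activation in pregnant mice was compared in the pregnancy set, ACTP against MuSCP. Nnat, an imprinted membrane protein of neurons, held 4.25% ± 4.91 (n = 4) in ACTP and 56.1% ± 48.5 (n = 4) in MuSCP (adjusted p 0.0603). Grb10, an imprinted brake on insulin signalling, held 8.03% ± 9.59 (n = 4) against 55.5% ± 40.3 (n = 5, adjusted p 0.0603), and Gnas, an imprinted G protein locus, 8.38% ± 8.40 (n = 4) against 53.6% ± 33.2 (n = 4, adjusted p 0.0615). Mstn, the inhibitor of muscle growth, held 65.6% ± 8.97 (n = 4) against 93.0% ± 7.15 (n = 5, adjusted p 0.111), and Col5a1 15.7% ± 18.3 (n = 4) against 57.5% ± 29.8 (n = 4, adjusted p 0.0685). Limma called 0 of 1143 regions (597 unadjusted), with 1142 means lower in ACTP and 272 regions without overlap (23.8%), and this set too was chosen on these libraries. The count of 0 was not stable, since it was 14 to 226 without any 1 MuSCP library, 28 over regions with every value and 312 with filled cells kept. Over 339 regions the mean was 22.4% ± 2.08 in ACTP and 55.7% ± 3.11 in MuSCP, a difference of −33.3 points (exact permutation p 0.0159, adjusted 0.0278).

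Imprinted genes were frequent in the pregnancy set. They held 14 of 1102 clusters, against 15 of 5476 in the de novo and demethylation sets together (odds ratio 4.685, Fisher's exact p 8.097e-05, two-sided, adjusted 0.001295 over 16 lists), and no other list passed (lowest p 0.1858, adjusted 0.8823). The 18 regions lay at Nnat, Gnas, Peg10, Nap1l5, Igf2, Kcnq1, Rasgrf1, Plagl1, Grb10, Rtl1, Igf2r and Impact, 14 of them within the gene. Averaged in each library over the regions with a value, all 18 in ACTP and 17, 17, 11, 17 and 18 in the MuSCP libraries, their mean was 8.43% ± 3.95 (n = 4) in ACTP and 40.8% ± 15.1 (n = 5) in MuSCP, a difference of −32.3 points (two-sided exact permutation p 0.0159, the smallest possible). The pregnancy set was chosen for a lower mean in ACTP on these libraries, so this direction and p are not independent evidence. Over 339 regions of the whole set the difference was −33.3 points. The tissue libraries stood between 32.8% and 49.4% at the imprinted regions. ACTP was below every tissue in 16 of the 18 regions, and in 77.3% of all regions of the set.

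**Figure D5:**
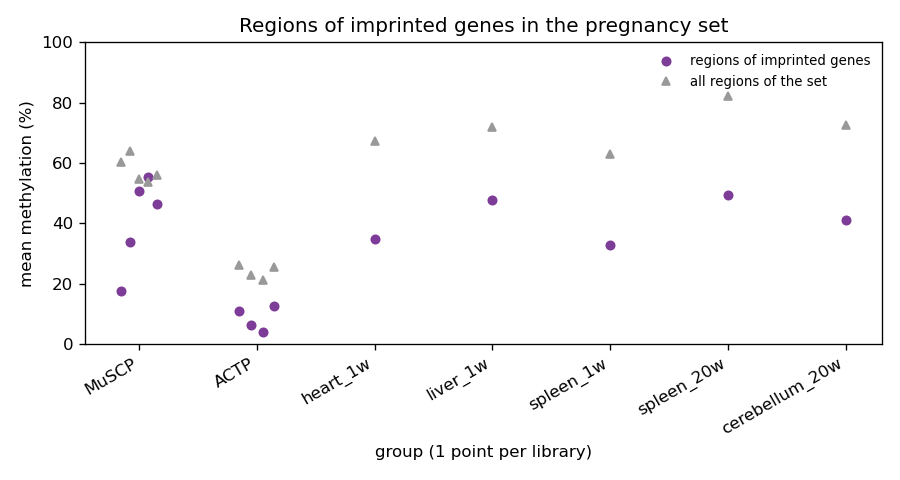
Mean methylation (percent, vertical axis) of the 18 imprinted-gene regions (circles) and of all regions of the pregnancy set (triangles), with 1 point per library and no error bars. The ACTP libraries lay between 3.92% and 12.5% at the imprinted regions, and the MuSCP libraries between 17.7% and 55.3%.

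The gene lists gave the following calls in ACT against MuSC, and since the study chose the regions on these samples the counts adjusted over the list alone are not independent evidence either. Among myogenic regulators, 3 of 4 de novo regions were higher and 2 of 8 demethylation regions lower, and adjusted over the list alone 3 and 1. Sarcomere and costamere genes, with Ldb3 in the de novo and Myom1 and Myl4 in the demethylation set, gave 4 of 7 and 6 of 9, and excitation genes 3 of 5 and 3 of 7, with the same counts adjusted over the list alone. Quiescence genes, with Nfix higher, gave 5 of 7 and 3 of 7 (list alone 5 and 2). The Notch list gave 5 of 5 and 2 of 6, the Wnt list, with Wnt11 higher and Axin2 lower, 6 of 7 and 5 of 6, the TGF beta and BMP list, with Smad5 and Smad6 higher, 6 of 9 and 1 of 2, and growth factors 4 of 6 and 3 of 7, unchanged over the list alone. Cell cycle genes gave 1 of 4, at Trp73, and 0 of 2. The DNA methylation machinery gave Tdg, a DNA glycosylase (69.1% ± 6.45 against 34.9% ± 24.8, n = 5 each, adjusted p 0.0136), and 2 of 3 demethylation regions, with Mbd2, a reader of methylated DNA, among them. Energy metabolism gave 4 of 7 and 7 of 9, immune markers 2 of 5 and 6 of 6, with Runx1 higher and Itgam lower, fibro-adipogenic markers 3 of 3 and 3 of 5, with Twist2 higher and Dpt lower, and imprinted genes 4 of 7 and 6 of 11. Endothelial and mural markers gave 0 of 1, at Tek (82.2% ± 31.3 against 57.7% ± 43.2, adjusted p 0.211), and 3 of 4, with Kdr and Emcn lower (list alone 0 and 4). Developmental transcription factors gave 19 of 30 and 12 of 32 (list alone 19 and 10). None of the lists differed in frequency between the de novo and demethylation sets (lowest Fisher's exact p 0.0731, TGF beta and BMP with 9 and 2 clusters, adjusted 0.903). In the pregnancy set limma called 0 regions of any list with all libraries in the model, a count that varied with single libraries for the set as a whole, and adjusted over the list alone 2 at quiescence genes (Tenm4 and Col5a1), 1 at the Wnt list (Wnt7b) and 2 at immune markers.

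The de novo and pregnancy sets shared 17 regions and the demethylation and pregnancy sets 16. At the 17 regions MuSC stood at 21.5% ± 2.61 (n = 5), ACT at 57.2% ± 5.65 (n = 5), MuSCP at 67.0% ± 4.75 (n = 5) and ACTP at 28.0% ± 2.85 (n = 4). These opposite directions follow from the choice of the sets, one for a higher mean in ACT and the other for a lower mean in ACTP. At the 16 regions MuSC stood at 62.0%, ACT at 30.1%, MuSCP at 54.0% and ACTP at 22.5%. The demethylation set held 48.5% of the 33 shared regions (exact 95% interval 30.8 to 66.5) and 46.5% of all regions of both sets (two-sided exact binomial p 0.863).

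The other tissues lay above ACT in both sets. Heart averaged 75.3%, liver 78.5%, the spleens 68.2% and 87.6% and the cerebellum 82.5% in the de novo set, where ACT averaged 59.0% ± 0.71 (n = 5) and muscle 59.4% ± 1.76 (n = 4). Their demethylation means were 69.2%, 70.6%, 62.6%, 77.1% and 78.9%, where MuSC averaged 67.8% ± 2.91 (n = 5) and ACT 32.4% ± 1.68 (n = 5). In the pregnancy set they averaged 67.4%, 71.8%, 62.9%, 82.4% and 72.7%, where MuSCP averaged 57.7% ± 4.29 (n = 5) and ACTP 23.9% ± 2.37 (n = 4).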

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

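All tests of explanations in this part, and the counts over other splits of the samples, were chosen after the results were seen.

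Every group of satellite cells in these sets other than MuSC, and muscle, lay nearer to ACT than to MuSC in both sets, including the contralateral cells CSC and the serum group Ser_inj, while the 5 other tissue libraries stood nearer to MuSC in the demethylation set. DNA of muscle fibres in the ACT libraries, from cells sorted VCAM1 positive, cannot be told apart from activation. The demethylation set would need 129% of it, but the choice of regions on ACT alone places ACT beyond other groups. Across regions, ACT minus CSC followed muscle minus CSC_2mo with slopes of 0.0561 (de novo) and 0.153 (demethylation). The slope that muscle DNA would give was not computed. In the demethylation set the lower spleen differed from MuSC by only −3.22 points, and by −3.52 outside the neighbouring pairs. In cells sorted negative for CD45, this argues against DNA of spleen or blood cells only if it reads as in these libraries. That is not known, since the tissue libraries had median sums of 147.5 to 187 points in the pairs, unlike the ACT libraries. Regions chosen on chance values of MuSC and ACT remain open, because the MuSC libraries correlated at −0.0459 and −0.0715 across the de novo and demethylation regions once the other groups' level was taken out. These values lay less far below 0 than the −0.119 and −0.132 of simulated choice on chance alone. Choice of regions with a real difference of the cells was not simulated, so the sign does not separate these explanations. A second candidate explanation is unmethylated cytosine filled in at the ends of MspI fragments during end repair, so that a region such as that of Taf5l reads as methylated in the molecules of 1 strand only, and 36.9% of library values in neighbouring opposite regions of the 37 satellite cell and muscle libraries added up to within 1 point of 100, with no upper quartile above 100 among these libraries. Both may act together, since the balance of strands varies most where few molecules were read, and a biological difference between MuSC and every other group stays open and untested.

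MuSC_2mo lay nearer to ACT than CSC_2mo did in both sets, at 85.4% and 72.6% of the ACT shift in the de novo set. With CSC_2mo as the baseline, DNA of muscle fibres in the MuSC_2mo libraries would need a share of 42.2% in the de novo set and 212% in the demethylation set. The latter divides by a muscle minus CSC_2mo difference of only −2.04 points, taken across separate deposited tables. These shares therefore cannot decide on muscle DNA. The groups come from separate deposited tables, 0 groups have libraries in both kinds of table, and the injury and the table therefore cannot be told apart. An effect of injury that differs between limbs stays open, as untested.

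At the 17 regions shared by the de novo and pregnancy sets, ACTP minus MuSCP was −39.1 points, while each ACT library lay above each MuSC library, directions that the choice of the sets fixed, and the difference between these changes was not tested. Regions chosen on chance values in both comparisons remain open, since the demethylation set held 48.5% of the shared regions, near the 46.5% that its size gives. Exchanged labels of ACTP and MuSCP cannot be told apart from the labels as given, because the interval of that percentage, from 30.8%, holds the share that chance choice gives under either labelling. A biological difference of activation between virgin and pregnant mice stays open, as untested.

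In 4 tests with an adjusted p below 0.05, MuSC_2mo minus MuSC was set against the same kind of contrast in other groups. Their permutation assumes no difference within either contrast, so they do not show that the contrasts differ from each other. In the de novo set MuSC_2mo minus MuSC exceeded MuSCP_2mo minus MuSCP by 29.9 points and CSC_2mo minus CSC by 26.8 points. The demethylation differences were −26.0 and −31.7 points. The baseline MuSC, on which the regions were chosen, enters only the first of each pair of contrasts and enlarges it, so these tests do not separate biology from the choice of regions.

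Single libraries were flagged as apart from the others of their group in 10 of 56 groups looked at. The chance rate of about 1 in 20, or 2.8 groups, holds for values without ties. At most of the flagged regions the other libraries all stood at 0% or all at 100%. Any departure is flagged there, so that rate is no measure of these flags. The lowest MuSC library averaged 20.7% over the de novo set, with the others between 23.7% and 24.9%. At demethylation regions 1 MuSC library each stood at 54.4% at Recql, 57.8% at Ldc1, 39% at Dnajc6 and 64.9% at Ddx1, with the others at 97% or above. At de novo regions 1 MuSC library each stood at 55.2% at Lipc, 36.1% at Lgr6 and 18.7% at Agbl2, with the others at 0%. In ACT 1 library stood at 100% at Etv6, with the others between 57.7% and 66.7%, and 1 at 95.7% at Clcn4, with the others at 100%.

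Other splits of the same libraries were counted for each number of called regions. In the de novo set ACT against MuSC gave 2088 regions and at most 130 in the other splits (1 of 100 splits reached the real count), MuSC_2mo 1024 and at most 618 (1 of 100), muscle 1561 and at most 953 (1 of 100), CSC 26 and at most 7 (1 of 56) and MuSCP_2mo 80 and at most 24 (1 of 100). For demethylation regions ACT against MuSC gave 1659 and at most 85 (1 of 100), MuSC_2mo 816 and at most 597 (1 of 100), muscle 547 and at most 423 (1 of 100), CSC 39 and at most 26 (1 of 56), Ser_inj 26 and at most 8 (1 of 100), MuSCP 83 and at most 23 (1 of 100) and MuSCP_2mo 173 and at most 83 (1 of 100), and Ser_inj against ACT 3 and at most 0 (1 of 100). Since the regions were chosen on MuSC and ACT, these splits do not exclude choice of the regions as the reason. Chance was not excluded for MuSCP against MuSC in the de novo set, with 6 regions and up to 19 in the others (6 of 100 splits), or for MuSCP_2mo against MuSCP, with 3 and up to 22 (40 of 100). The region at Ociad2 in muscle against CSC_2mo was the only one called, with 0 in the others (1 of 35 splits, the smallest share possible). That call was lost without any 1 muscle library, and the count was 0 on the logit scale, with centred libraries and with filled cells kept but 4 over regions with every value and 112 with only these groups in the model, so no weight rests on it.

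Where limma called 0 regions, every split reached that count. Among de novo regions the highest of the others was 1 for MuSC_2mo against ACT and 2 for muscle against ACT (100 of 100 splits each), 1 for CSC_2mo against MuSC (56 of 56), 6 for Ser_inj against MuSC (100 of 100), and 0 for CSC (56 of 56), Ser_inj and MuSCP (100 of 100 each) against ACT and for MuSC_2mo against CSC_2mo (35 of 35). In the demethylation set it was 1 for MuSC_2mo and 0 for muscle against ACT (100 of 100 each), 5 for CSC_2mo against MuSC (56 of 56), 12 for MuSCP_2mo against MuSCP (100 of 100), 0 for CSC (56 of 56) and MuSCP (100 of 100) against ACT, and 0 for MuSC_2mo and muscle against CSC_2mo (35 of 35 each). CSC_2mo against CSC has 10 splits, too few for a share under 0.05, with 0 regions in the real split and 0 at most in the others in both sets. In the pregnancy set ACTP against MuSCP gave 0 regions and another split 55 (100 of 100), with 0 at the median of the others. Which splits gave the highest counts, and how near they lay to the real groups, was not examined.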

How the results depend on the processing

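The alternatives were fixed before the data were examined, except filled cells kept as deposited, the omission of MuSCP libraries 1 and 2, and the comparisons with CSC_2mo, which were added after the results were seen. The depth of each value is unknown, so no minimum of coverage could be tried. Mean differences kept their direction and side of the threshold in all 35 comparisons with regions within 1 kb averaged and without X and Y, and so did all 35 counts at a difference of 10 points or more. None of the 16 lists differed in frequency between the de novo and demethylation sets within 10 kb or by single region either. The odds ratio of quiescence genes went from 0.862 to 1.006 within 10 kb. The excess of imprinted genes in the pregnancy set was not run under these alternatives. With MuSC in 2 parts, the shares of the ACT shift moved by less than their bootstrap SD. Libraries centred by their median were not run for the pregnancy set. Where a change follows from fewer regions or fewer samples this is said, and elsewhere the cause was not tested.

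Per region, the exact permutation test called 0 regions in each of 16 comparisons with limma calls. Its smallest p is 0.00794 with 5 libraries against 5 and larger with fewer or with missing values, and whether this alone was the cause was not tested. These were ACT, CSC, MuSCP, MuSCP_2mo, MuSC_2mo and muscle against MuSC, MuSCP_2mo against MuSCP and muscle against CSC_2mo in the de novo set, and ACT, CSC, MuSCP, MuSCP_2mo, MuSC_2mo, Ser_inj and muscle against MuSC and Ser_inj against ACT in the demethylation set. Of 165 named regions, 58 kept their call or lack of one there and 107 lost it.

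The replicate numbers do not pair the libraries in any comparison, as the best correlation of libraries with the same number was 0.0824. With replicate block as a term, the called counts were 0 for ACT, CSC, MuSCP, MuSCP_2mo and MuSC_2mo against MuSC, MuSCP_2mo against MuSCP and muscle against CSC_2mo in the de novo set, and 0 for ACT, CSC, MuSCP, MuSCP_2mo, MuSC_2mo, Ser_inj and muscle against MuSC and Ser_inj against ACT in the demethylation set, with 1 for muscle against ACT. Paired sign flips of the means cannot go below 0.0625 with 5 pairs, 0.125 with 4 and 0.25 with 3, so 26 mean differences were no longer past the threshold by construction. In the de novo set these were 34.7 for ACT, 23.6 CSC, 25.9 CSC_2mo, 22.9 MuSCP, 22.5 MuSCP_2mo, 29.2 MuSC_2mo, 25.0 Ser_inj and 34.3 muscle against MuSC, and −10.8 CSC, −10.7 MuSCP, −4.87 MuSC_2mo and −9.02 Ser_inj against ACT. The demethylation values were −34.5 for ACT, −28.1 CSC, −27.2 CSC_2mo, −25.2 MuSCP, −28.1 MuSCP_2mo, −30.4 MuSC_2mo, −27.8 Ser_inj and −27.5 muscle against MuSC, and 8.78 CSC, 8.68 MuSCP, 6.44 MuSC_2mo, 8.01 Ser_inj and 8.36 muscle against ACT. In the pregnancy set ACTP minus MuSCP was −33.6.

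With only the 2 groups in the model, the spread came from those groups alone, and counts moved in both directions. The model shares a single spread per region between its groups, while the SD between libraries differed by group. Taken over regions, this SD was 27.6 points in MuSC, 17.8 in ACT and 8.91 in muscle in the de novo set. The demethylation values were 31.2, 16.6 and 8.80. In MuSC_2mo the SD was 19.9 and 18.6 points, so MuSC had the largest SD in the model of MuSC, ACT, MuSC_2mo and muscle. The shared spread there lies below that of MuSC, and adjusted p-values against MuSC may be too small. The counts of ACT and MuSC_2mo against MuSC were lower in both sets with only the 2 groups. How much of these changes came from the shared spread was not tested. De novo counts became 42 for CSC, 3 CSC_2mo, 0 MuSCP, 33 MuSCP_2mo, 503 MuSC_2mo and 63 Ser_inj against MuSC, 19 CSC, 1 MuSC_2mo, 5 Ser_inj and 9 muscle against ACT, 0 for MuSCP_2mo against MuSCP and 112 for muscle against CSC_2mo. Demethylation counts became 718 for ACT, 0 CSC, 7 MuSCP, 30 MuSCP_2mo, 121 MuSC_2mo, 9 Ser_inj and 305 muscle against MuSC, 3 CSC, 1 MuSC_2mo, 9 Ser_inj and 69 muscle against ACT, and 4 MuSC_2mo and 56 muscle against CSC_2mo.

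With only regions that had every value, fewer regions were tested. De novo counts were 639 for ACT, 7 CSC, 20 MuSCP_2mo, 319 MuSC_2mo and 512 muscle against MuSC, 1 MuSC_2mo and 4 muscle against ACT and 4 for muscle against CSC_2mo. Demethylation counts were 512 for ACT, 5 CSC, 26 MuSCP, 33 MuSCP_2mo, 268 MuSC_2mo, 10 Ser_inj and 229 muscle against MuSC and 1 for Ser_inj against ACT. The pregnancy set gave 28.

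With filled cells kept as deposited, de novo counts were 60 for CSC, 50 MuSCP_2mo and 57 Ser_inj against MuSC, 1 for MuSC_2mo against ACT and 0 for muscle against CSC_2mo. Demethylation counts were 111 for CSC, 202 MuSCP, 322 MuSCP_2mo, 112 Ser_inj and 843 muscle against MuSC and 1 for MuSC_2mo against CSC_2mo. The pregnancy set gave 312. The demethylation mean of MuSCP_2mo minus MuSCP passed the threshold at −2 points with filled cells kept and at −2.002 points over every region with a value (exact permutation p 0.0476 each), and the cause was not tested.

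With libraries centred by their median, de novo counts were 0 for MuSCP, 151 MuSCP_2mo and 739 muscle against MuSC, 5 for MuSCP_2mo against MuSCP and 0 for muscle against CSC_2mo, and demethylation counts 66 for MuSCP_2mo, 64 Ser_inj and 1210 muscle against MuSC. On the logit scale, de novo counts were 26 for MuSCP against MuSC, 18 for MuSCP_2mo against MuSCP (9 of them higher) and 0 for muscle against CSC_2mo, and demethylation counts 1088 for ACT, 1 CSC_2mo, 9 Ser_inj and 356 muscle against MuSC and 28 for MuSCP_2mo against MuSCP (12 higher). Averaging within 1 kb gave 125 demethylation regions for MuSCP against MuSC. The cause was not tested.

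With medians over regions, muscle minus ACT was −0.290 points in the de novo set, the reverse of the mean, and the demethylation differences of 2.83 for CSC and 4.28 for MuSCP against ACT no longer passed. Shares of the ACT shift became 80.4% for CSC_2mo, 71.3% MuSCP_2mo, 89.1% MuSC_2mo, 78.8% Ser_inj and 96.3% muscle in the de novo set, and 91.0% for CSC, 75.4% CSC_2mo, 89.0% MuSCP, 103% MuSCP_2mo, 86.9% MuSC_2mo and 82.3% Ser_inj in the demethylation set. The cause was not tested.

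Leaving out 1 library at a time left 252 mean differences on their side of the threshold and moved 48 below it, all in comparisons with CSC or CSC_2mo where fewer samples remain. De novo differences ran from −11.3 to −9.93 for CSC against ACT, 21.6 to 24.1 for CSC against MuSC and 24.9 to 26.2 for CSC_2mo against MuSC, and demethylation differences from 7.20 to 8.76, −27.5 to −25.3 and −25.8 to −24.8. MuSCP_2mo minus MuSCP ran from −5.24 to 0.0198 in the de novo set, reversed without MuSCP_2mo library 2. Ccnb2 ran from −27.9 to 5.47, reversed without MuSC library 3. Shares ran from 64.9% to 71.4% for CSC and 70.9% to 74.8% for CSC_2mo and 62.9% (without MuSCP 5) to 72.9% (without MuSCP 1) for MuSCP in the de novo set, and 71.9% to 78.1% for CSC in the demethylation set.

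Counts for the pregnancy set ran from 0 to 226, with 226 without MuSCP library 1, 125 without 2, 14 without 3, 204 without 4 and 110 without 5. In the de novo set, CSC against MuSC ran from 0 to 22, with 0 without MuSC libraries 1, 2 or 5, 7 without MuSC 3, 16 without MuSC 4 and 3 without CSC 3. MuSCP against MuSC ran from 0 to 62, with 0 without MuSC 1, 2 or 3 or MuSCP 2, 3 or 4, 24 without MuSCP 1, 62 without MuSCP 5, and 2 without MuSCP 1 and 2 together. MuSCP_2mo against MuSC ran from 18 to 106, with 50 without MuSC 1, 18 without MuSC 3 and 53 without MuSC 4. MuSCP_2mo against MuSCP ran from 0 to 12, with 0 without MuSCP 2 or 4 or MuSCP_2mo 2, and 5, 6 and 12 without MuSCP_2mo 1, 3 and 4. Ranges of 0 to 1 were found for CSC_2mo against CSC (1 without CSC 1), MuSC_2mo against ACT (1 without ACT 2 or 5), Ser_inj against MuSC (1 without MuSC 4) and muscle against CSC_2mo (0 without any muscle library or CSC_2mo 1 or 2), and 0 to 2 for muscle against ACT (2 without ACT 1, 1 without ACT 2).

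In the demethylation set, CSC against MuSC ran from 0 to 64, with 64, 0, 63 and 62 without MuSC 1, 2, 3 and 4 and 0, 22 and 0 without CSC 1, 2 and 3. CSC_2mo against MuSC ran from 0 to 2, with 2 without MuSC 5 and 1 without CSC_2mo 1. MuSCP against MuSC ran from 39 to 145, with 46, 54, 39, 41 and 145 without MuSCP 1 to 5 and 4 without MuSCP 1 and 2 together. MuSCP_2mo against MuSC ran from 87 to 190, with 94 without MuSC 3 and 87 without MuSCP_2mo 3. MuSCP_2mo against MuSCP ran from 0 to 34, with 1 and 34 without MuSCP 1 and 5 and 4 and 9 without MuSCP_2mo 1 and 4. Ser_inj against ACT ran from 0 to 1, with 1 without any ACT library or Ser_inj 1 and 0 without Ser_inj 2, 3 or 4. Ser_inj against MuSC ran from 0 to 43, with 43, 17, 17 and 7 without MuSC 1, 2, 4 and 5, 0 without Ser_inj 1, 2 or 3 and 1 without Ser_inj 4. Muscle against MuSC ran from 252 to 653, with 274, 252, 258 and 268 without muscle 1 to 4.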

Other observations

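The pairing of neighbouring regions was found and tested after the data were examined. Neighbours of the opposite sets were 136 of 210 where starts lay 100 bp apart, 204 of 214 at 200 bp, 40 of 46 at 300 bp and 16 of 26 at 400 to 1000 bp. At Ldc1 ACT stood at 57.8% ± 13.01 in the de novo region and 20.0% ± 14.7 in the demethylation region 200 bp away (n = 4 each), and at Ddx1 at 48.7% ± 23.3 and 23.1% ± 14.1 (n = 5 each). The de novo regions of the pairs averaged 79.9% over the 5 tissue libraries and 48.0% over the satellite cell and muscle libraries, where the demethylation regions averaged 41.7%. If fill-in of MspI ends is the source, as the 36.9% of sums within 1 point of 100 (6.25% to 71.3% by library) may suggest, the level of a region could follow the balance of strands at a methylated fragment, and the de novo and demethylation labels would name its ends. ACT stood at 58.8% and 31.3% in the pairs, so the strands would not be balanced in every group. MspI sites were not placed, because no genome sequence was used here.

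The imprinted regions of the pregnancy set were looked at one library at a time after their excess was seen. The MuSCP means were 17.7%, 33.9%, 50.6%, 55.3% and 46.3% in libraries 1 to 5, over the 17, 17, 11, 17 and 18 regions with a value, and the ACTP means 10.9%, 6.42%, 3.92% and 12.5%. Libraries 1 and 2 of MuSCP thus lay below the tissue libraries or among the lowest of them, at 32.8% to 49.4%. Values at exactly 0 or 100 made up 1.22% to 49.2% of the MuSCP libraries in this set and 5.09% to 67.6% in the de novo set. In MuSC they made up 27.7% to 59.0% of the de novo set.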
